A study of Bombyx mori with 4 samples.

How the data were processed

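The deposited data are scanner text files of 4 custom Bombyx mori arrays on 1 slide, made per the file headers with Feature Extraction 10.7.3.1 and protocol GE2_107_Sep09, and hold signals in both dyes as intensity and a LogRatio column in log10. The series design text calls the arrays one-color, while every file holds both a Cy5 and a Cy3 channel and the labels name a sample for each, so they were treated as 2-colour arrays. Per the labels, Cy5 was diapause eggs and Cy3 non-diapause eggs on every array, RNA was total RNA extracted with TRIzol, and labelling was by Quick-Amp with oligo-dT priming. The race is given as MW13 in the sample characteristics and as M13 in the growth protocol. The deposited series values are in log2 of Cy5 over Cy3 and correlated across probes with the deposited LogRatio column at 0.979, 0.991, 0.99 and 0.993 on the 4 arrays, with medians of 0.22, 0.16, 0.1 and 0.1, and the authors do not state its normalization.

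Of 45220 spots per array, 43803 were not controls, for 24924 probes. Mean signals were corrected with the normexp method of limma 3.58.1 and an offset of 50, using the median local background, and log2 ratios were normalised within each array by loess on intensity with controls given no weight. Spots marked as outliers per the scanner files (9, 8, 32 and 59 spots on the 4 arrays) were left out, and spots were averaged per probe. Probes were kept where a channel was well above background on both arrays of at least 1 time. This left 13023, of which 13019 had a value on each array. Gene symbols came from a RefSeq gene table of assembly ASM3026992v2, used for names alone: 2902 probes carried a RefSeq accession, 2839 were matched and 1861 had an informative symbol, for 1194 genes. Positions were not assigned, and 3102 probes were named as cross-hybridising in the array annotation.

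Diapause and non-diapause eggs were compared with a limma fit of group means to the log2 ratios of the 4 arrays, with moderated variances and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 counted as passing. Changes over time within a kind of egg used limma's separate-channel fit after Aquantile normalization between arrays, with a spot correlation of 0.292. With 3 arrays this correlation cannot be estimated, so fits without 1 array used the value from all 4. All tests were two-sided. A fold given as at least N-fold is for a gene not well above background on either array of the dimmer group. It set the mean of the brighter group against the dimmer one, taking on each array the higher of the gene's own signal and the lowest signal that was well above background in that channel.

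The 30 gene lists with measured members were tested with limma's camera, with a preset correlation of 0.01, on the brightest probe per gene, and for changes over time with its version for ranked statistics on the moderated statistics of the channel fit. Lists of fewer than 3 genes were not tested, which left 27 lists. Members said to pass adjusted over the list alone were adjusted within each list, with no correction across lists or comparisons. Each call was set against camera with an estimated correlation and against fry, and for changes over time these ran on the channels of that kind of egg alone. The lists had been planned as searches of gene descriptions, which are all given as unknown, so members were chosen by symbol after the annotation was seen and before any ratio was computed. The list of transposable elements had no members, and sorbitol dehydrogenase and ecdysteroid-phosphate phosphatase were not among the named genes.

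Genes were named by a rule written before the data were examined. In each comparison of the eggs, 8 genes per direction were taken among those past the threshold with the same sign on both arrays, and 5 per direction for the difference and the changes over time. Where fewer passed, all that passed were taken, and where none did, the 3 per direction with the smallest p were taken and are said not to pass. Up to 4 members of each list were added by the size of the limma statistic, and glycogen phosphorylase, Time, Samui, PBAN, trehalase and Hsp70 or Hsc70 genes were always given. Of the genes this rule allows, the text names a part, chosen after their values were seen.

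In simulated data of 50 probes per fold with the noise of these arrays, the fit at 30 h recovered 80% of 8-fold changes. Changes of 1.5, 2, 4 and 8-fold were set together in the same simulated data, with independent probes. The share recovered depends on how many probes change. A simulated list of 40 members was shifted on all 4 arrays and tested at 30 h. It had an adjusted p of 1.51e-05 in camera with the preset correlation, 0.744 with an estimated correlation and 0.351 in fry. The absence of calls in the last pair of tests thus does not show that a list is unshifted. The members were drawn independently, so the simulation does not show that the preset correlation holds for genes that move together on an array. The software was R 4.3.3, limma 3.58.1, version 1.17.8 of data.table and jsonlite 2.0.0, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for the figures.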

Results

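Eggs of the silkworm Bombyx mori that had been induced to enter diapause, the arrest of embryonic development by which eggs of this species pass an unfavourable season, were compared with non-diapause eggs at 18 h and at 30 h after oviposition. The comparison asked which transcripts differ between the eggs at each time and how each kind of egg changes from 18 h to 30 h. Total RNA of both kinds of egg was hybridised together on each of 4 arrays, 2 at 18 h and 2 at 30 h, with diapause eggs in Cy5 and non-diapause eggs in Cy3 on every array. Of 24924 probes, 44.3% and 49.2% were well above background in the diapause channel of the 18 h arrays, and 51.5% and 37% in that of the 30 h arrays. In the non-diapause channel the shares were 56.6% and 49.8% at 18 h and 53.3% and 44.7% at 30 h. The tests covered 13019 probes, and 1210 of the 13023 probes kept by the filter had an informative gene symbol, for 781 genes, so most probes stayed unnamed. Log2 ratios are diapause over non-diapause throughout, so that positive values are higher in diapause eggs, and values after ± are standard errors from limma. No array had its dyes swapped, so a dye effect of a single probe is part of every ratio at 1 time and cancels in the difference between the times. The 2 arrays of a time had little in common across probes, which are not independent replicates: the correlation of their log2 ratios was 0.108 at 18 h and 0.162 at 30 h. The labels do not say whether replicates came from separate egg collections, so the p-values measure the spread between these samples only, and the number of arrays limits the precision.

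At 18 h after oviposition, the mRNAs of cytoplasmic ribosomal proteins, the protein part of the ribosome, had less signal in diapause eggs than in non-diapause eggs. No gene of this paragraph passed over all probes, and only camera with the preset correlation called this list. Of 74 measured genes of this list, 66 lay below 0, with a median log2 ratio of -0.35, and the medians on the arrays of replicates 1 and 2 were -0.33 and -0.44. Members included RpS29 at -1.58 ± 0.24 (SE, n = 2 arrays) and RpL29 at -1.44 ± 0.25, with RpS30 at -0.93 ± 0.18 and RpL34 at -0.91 ± 0.16. In the other direction, DnaJ-5, a co-chaperone of the Hsp40 family, was 3.6-fold higher in diapause eggs (log2 ratio 1.85 ± 0.29, n = 2 arrays). SPZ1, a Spätzle ligand of the Toll pathway, was 2.3-fold higher (1.20 ± 0.21).

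The shift of the ribosomal protein list passed the test of limma's camera with a preset correlation (adjusted p = 1.37e-09) and was lost with an estimated correlation (adjusted p = 0.894) and in fry (adjusted p = 0.772). None of its 74 members passed over all probes or adjusted over the list alone, and 59 of the 74 probes were saturated on at least 1 array. Without probes saturated on any array, the adjusted p of the list was 7.6e-06. On the 30 h arrays the medians of the list were -0.64 and 0.37, a spread within 1 time wider than its shift at 18 h. Its members can thus move together on an array, and the p-value of camera does not measure the spread between samples.

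No single probe passed at 18 h in limma (0 of 13019, smallest adjusted p = 0.537). Of the probes, 983 had an unadjusted p under 0.05, of which 498 were higher and 485 lower, against 651 by chance. The count was 0 in every other limma fit that was run. A ratio of at least 2-fold in the same direction on both arrays was found for 15 probes higher and 78 lower in diapause eggs, where unrelated arrays would give 8 and 20, and 52 probes were at least 2-fold in opposite directions. In simulated data with the noise of these arrays, the fit at 18 h found 82% of 50 probes changed 8-fold, 36% of those changed 4-fold and 0% of those changed 2-fold. These shares depend on how many probes change, so the count of 0 does not rule out large differences.

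Of 15 translation factors, 9 lay above 0 (camera adjusted p = 0.624), among them eIF3-S9 at 0.81 ± 0.14 (n = 2 arrays) and eIF3i at 0.63 ± 0.19, subunits of an initiation factor. Kr-h1, a transcription factor that responds to juvenile hormone, stood at -1.14 ± 0.21, within a juvenile hormone list of which 11 of 22 members lay above 0 (adjusted p = 0.749; the median and the test pointed up and the mean down). MLC-2, a myosin light chain, stood at -1.01 ± 0.21 and was the only member of any list to pass adjusted over the list alone at this time. The cuticle gene CPH30 stood at -1.49 ± 0.32, and 41 of 73 genes for cuticle and chitin lay below 0 (adjusted p = 0.448). The neuropeptide receptor gene NGR-A11 was at -1.55 ± 0.32, with 29 of 51 genes of the nervous system list below 0 (adjusted p = 0.645). That list also holds genes for odorant-binding and chemosensory proteins, so it does not stand for neural genes alone. On the arrays of replicates 1 and 2, 15 and 34 nervous system genes lay below 0. For cuticle and chitin these counts were 33 and 45, and for melanin 3 and 9. E75, a nuclear receptor induced by ecdysone, stood at 0.59 ± 0.18, and Run, the homologue of the pair-rule gene runt, at 0.63 ± 0.18. Further lists with most mean ratios below 0, which for the cell cycle rests on replicate 2 (13 of 15 below 0, against 8 on replicate 1), were the cell cycle and DNA replication with 12 of 15 (adjusted p = 0.228, Rpa3 at -0.85 ± 0.19) and yolk and egg proteins with 6 of 7 (0.228, Lp-c6 at -0.60 ± 0.18). The same held for the MAP kinase list with 7 of 10 (0.645) and the respiratory list of the TCA cycle and oxidative phosphorylation with 6 of 10 (0.645, Uqcr11 at -1.16 ± 0.29). PPO2, a prophenoloxidase, stood at -1.08 ± 0.29, the glutathione transferase gene GSTd2 at 0.56 ± 0.14 and Ubc13, a ubiquitin-conjugating enzyme, at 0.77 ± 0.19. None of the probes named in this paragraph passed over all probes, with adjusted p between 0.537 and 0.607. Of the lists not yet named, members above 0 numbered 8 of 23 for heat shock proteins and chaperones, 1 of 4 for histones, 3 of 11 for melanin, 10 of 17 for immune genes, 5 of 10 for germ line genes, 8 of 21 for the fat body and 3 of 6 for the proteasome (adjusted p = 0.645 for each, the proteasome median pointing down and its mean and test up). They numbered 14 of 29 for antioxidant genes (0.892), 4 of 12 for insulin signalling (0.375), 5 of 7 for lipid metabolism (0.448), 1 of 6 for muscle (0.228) and 0 of 3 for ommochrome and serosal pigment (0.624). For 7 of 19 patterning genes, 6 of 10 ecdysteroid genes and 7 of 13 autophagy genes (0.991 for each), median, mean and test did not share a sign.

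None of the genes with a known place in egg diapause passed at 18 h. Samui, whose product has been linked to the cold signal that ends diapause, stood at 0.40 ± 0.17 (n = 2 arrays), and Glyp, the glycogen phosphorylase that starts the breakdown of glycogen, at 0.38 ± 0.14. Treh-2, a trehalase, stood at -0.67 ± 0.27 and the clock gene Per at -0.57 ± 0.22, while PBAN, whose precursor also holds the diapause hormone, stood at 0.08 ± 0.36. Time, the esterase thought to measure the length of the cold period, stood at -0.44 ± 0.59, with values of 0.03 and -0.92 on the arrays of replicates 1 and 2. HSP70 at 0.05 ± 0.40 had opposite signs on both arrays and turned below 0 without background correction and with the deposited ratios, and Hsc70-4, saturated in diapause eggs, stood at -0.01 ± 0.54 and turned above 0 with median centring. Of the lists around these genes, 2 of 3 genes for polyols, glycogen and trehalose, 3 of 4 for diapause timing and 2 of 3 for the circadian clock lay above 0 (adjusted p = 0.645, 0.645 and 0.787), although the mean and the test of the clock genes pointed down.

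At 30 h, some genes of different kinds had more signal in diapause eggs, but no gene of this paragraph passed over all probes. Desat3, a fatty acid desaturase, was 14.1-fold higher (log2 ratio 3.82 ± 0.21, SE, n = 2 arrays). Other genes among those with the smallest p were Y-fa of the yellow family 7.15-fold (2.84 ± 0.30), AK 5.1-fold (2.35 ± 0.17), MLC-2 4.97-fold (2.31 ± 0.21) and the oxidation resistance gene oxr1 3.22-fold (1.69 ± 0.15). Lower in diapause eggs were hJHBP, a juvenile hormone binding protein of the haemolymph, at -2.45 ± 0.41, well above background on 1 of the 2 arrays in diapause eggs. Also lower were serpin-8, a serine protease inhibitor, at -1.58 ± 0.16, and Y14, a protein of the exon junction complex, at -1.07 ± 0.22. Each of these genes had the same sign on both arrays, which their choice by these same values favours. Of all probes tested, 53.5% shared a sign at 30 h. AK had a saturated spot in diapause eggs on 1 of the arrays. A ratio of at least 2-fold in the same direction on both arrays was found for 73 probes higher and 11 lower, where unrelated arrays would give 7 and 6, and 42 were at least 2-fold in opposite directions.

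No single probe passed at 30 h in limma over all probes (0 of 13019, smallest adjusted p = 0.16, that of Desat3). Of the probes, 472 had an unadjusted p under 0.05 (257 higher, 215 lower, 651 by chance), and the other limma fits also gave 0. Adjusted over the list alone, with no correction across lists, 8 members of the fixed lists passed: Desat3, Y-fa, MLC-2, Mef2, E75, BGRP4, serpin-8 and Tf. In simulated data, the fit at 30 h found 80% of 50 probes changed 8-fold and 26% of those changed 4-fold. These shares depend on how many probes change. In the data Desat3 did not pass with a ratio above 8-fold, so the count of 0 does not rule out large differences.

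**Figure D1:**
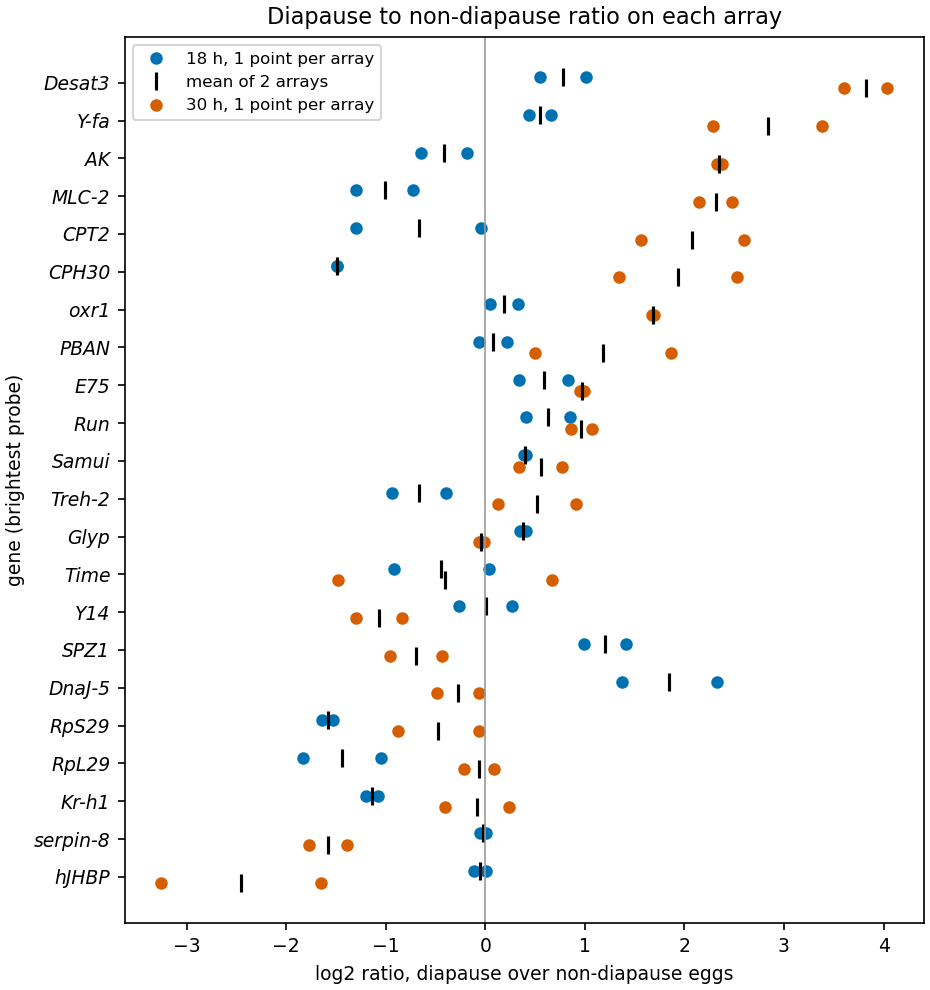
Log2 ratio of diapause over non-diapause eggs (horizontal axis) for 22 genes (vertical axis, brightest probe of each), with blue points for the 18 h arrays, orange points for the 30 h arrays and a black bar at the mean of 2 arrays. At 30 h Desat3 lay between 3.60 and 4.04 and hJHBP between -3.26 and -1.65, while both genes lay nearer 0 at 18 h.

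Of 73 genes for cuticle and chitin, 48 lay above 0 at 30 h with a median log2 ratio of 0.11. The medians were 0.21 on the array of replicate 1 and 0.01 on that of replicate 2. CPT2, a cuticle protein of the Tweedle family, stood at 2.08 ± 0.42 (n = 2 arrays), CPH30 at 1.94 ± 0.32 and CPR1 at 1.37 ± 0.34, and no member passed over all probes or over the list alone. The list passed camera (adjusted p = 0.0297) and was lost with an estimated correlation (adjusted p = 0.734) and without replicate 1 of 30 h (adjusted p = 0.739). On the array of replicate 1, 51 members lay above 0, against 41 on the array of replicate 2.

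Of 10 ecdysteroid genes, 9 lay above 0 at 30 h, 9 on the array of replicate 1 and 6 on that of replicate 2. E75 was at 0.97 ± 0.18 (n = 2 arrays), Cyp315a1, a P450 of ecdysteroid synthesis, at 0.75 ± 0.37 and PTTH, the hormone that stimulates this synthesis, at 0.44 ± 0.24. The last pair rests on replicate 1, since on the array of replicate 2 Cyp315a1 was at 0.05 and PTTH at 0.10. All 3 measured genes of the ommochrome and serosal pigment list lay above 0: Kmo, the kynurenine monooxygenase of ommochrome synthesis, at 1.01 ± 0.38, the pigment transporter gene wh3 at 0.36 ± 0.17 and Pts, of pteridine synthesis, at 0.18 ± 0.19, with 0.02 on the array of replicate 2. Of 17 immune genes, 10 lay above 0. Values were, for the C-type lectin CTL5 2.27 ± 0.49, with 1.31 on the array of replicate 2, the recognition protein BGRP4 1.88 ± 0.30 and cact, the homologue of the Toll pathway inhibitor cactus, 0.49 ± 0.13, while SPZ1 stood at -0.70 ± 0.21. These 3 lists passed camera with adjusted p = 0.0352, 0.0352 and 0.0478, and none held with an estimated correlation (adjusted p = 0.734 for each). With the replicate number as a block, the ommochrome and immune lists lost their calls. With the deposited ratios the adjusted p of the 3 lists was 0.271, 0.188 and 0.271, and with median centring it was 0.0537, 0.0781 and 0.0537. Leaving out the array of replicate 1 at 30 h gave 0.444 for the ecdysteroid list and 0.334 for the ommochrome list. Leaving out replicate 2 gave 0.102 for the ommochrome list and 0.0708 for the immune list, which was at 0.134 without either 18 h array.

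Ribosomal protein genes lay below 0 in 61 of 74 cases at 30 h, with a median of -0.13, but the arrays of that time did not share this direction. On the array of replicate 1, 63 of the 74 genes lay below 0 with a median of -0.64, and on that of replicate 2, 47 lay above 0 with a median of 0.37. The list passed camera as lower in diapause eggs (adjusted p = 0.0297) and lost the call with an estimated correlation (adjusted p = 0.734) and without saturated probes (adjusted p = 0.342). Without replicate 1 it turned higher (adjusted p = 1.12e-07). RpS2e stood at -0.80 ± 0.24 (n = 2 arrays), with -1.19 and -0.42 on the arrays of replicates 1 and 2, and RpL7A at 0.52 ± 0.14. At 30 h RpL7A was saturated on 1 array in diapause eggs and RpS2e on 1 array in each kind of egg.

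**Figure D2:**
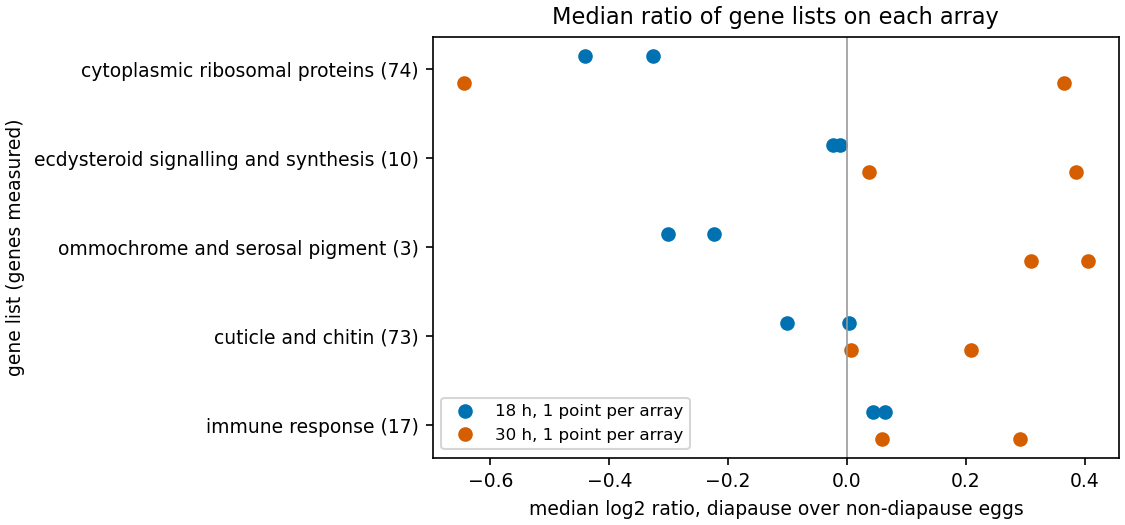
Median log2 ratio of diapause over non-diapause eggs (horizontal axis) on each array for the 5 gene lists that passed camera in a comparison of the eggs (vertical axis, genes measured in brackets), with blue points for the 18 h arrays and orange points for the 30 h arrays. The ribosomal proteins lay at -0.44 and -0.33 at 18 h and at -0.64 and 0.37 at 30 h.

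Among the lists that did not pass at 30 h, the muscle list came nearest, with 4 of 6 genes above 0 (adjusted p = 0.0559), 4 on replicate 1 and 2 on replicate 2, including MLC-2 and Mef2, a transcription factor of muscle, at 0.76 ± 0.18 (n = 2 arrays). Of 29 antioxidant and detoxification genes, 16 lay above 0 (0.285), with the P450 gene Cyp332a1 at 1.72 ± 0.42 and GSTd2 at 0.77 ± 0.14. Of 21 fat body and haemolymph genes, 12 lay above 0 (0.328), with the iron carrier transferrin, Tf, at 1.01 ± 0.16 and serpin-3 at 0.97 ± 0.22. The juvenile hormone list had 14 of 22 members above 0 (0.762), with Jheh2, an epoxide hydrolase of juvenile hormone, at -0.96 ± 0.25. Of 11 genes for melanin and sclerotisation, 7 lay below 0 and their median was -0.08, although the mean and the test pointed up (0.762), since Y-fa and Y-d, the latter at 2.11 ± 0.48, lay far above the rest. Y-d was at 2.986 on the array of replicate 1 and at 1.235 on that of replicate 2. In the remaining lists, Vgr, the vitellogenin receptor, stood at 1.26 ± 0.30, Run at 0.97 ± 0.18, the chemosensory protein gene CSP16 at 1.15 ± 0.19 and Nanoso, of the nanos family, at 0.81 ± 0.24. Of the yolk list that holds Vgr, 4 of 7 genes lay above 0 (0.552), 5 on replicate 1 and 2 on replicate 2. Of the germ line list that holds Nanoso, 6 of 10 lay above 0 (0.552), 6 and 4 on these arrays. Members above 0 numbered 3 of 10 for the TCA cycle (0.113), 30 of 51 for the nervous system (0.245), 0 of 3 for the circadian clock (0.28), 4 of 7 for lipid metabolism (0.596), and 9 of 13 for autophagy and lysosome (0.279). They numbered 1 of 6 for proteasome and ubiquitin (0.28), 12 of 19 for embryonic patterning (0.328), 12 of 23 for heat shock proteins and chaperones (0.894, median and mean up and test down) and 2 of 4 for histones (0.328).

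The diapause genes at 30 h included PBAN at 1.18 ± 0.36 (n = 2 arrays), Samui at 0.56 ± 0.17 and Treh-2 at 0.52 ± 0.27. On the arrays of replicates 1 and 2, PBAN was at 1.87 and 0.50, Samui at 0.77 and 0.34 and Treh-2 at 0.13 and 0.91. Glyp stood at -0.04 ± 0.14 and turned to 0.03 with median centring. Time at -0.40 ± 0.59, HSP70 at -0.50 ± 0.40 and Hsc70-4 at -0.06 ± 0.54 had opposite signs on both arrays, and Hsc70-4, saturated in diapause eggs on 1 array of 30 h, also turned above 0 without background correction, with median centring and with arrays scaled to one spread. None of the 7 genes passed (adjusted p = 0.999 for each). Lists with fewer than 3 measured genes were not tested: at 30 h Tpi and the other glycolysis gene lay below 0 (Tpi at -0.79 ± 0.23), as did both genes of the silk gland, a tissue absent from eggs, and the single chorion gene was at 0.07.

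Between 18 h and 30 h the ratio of diapause over non-diapause eggs differed by several fold in genes of different kinds, none of which passed. CPH30 differed by 3.43 ± 0.45 on the log2 scale (SE, n = 4 arrays), MLC-2 by 3.33 ± 0.29, Desat3 by 3.04 ± 0.29, AK by 2.76 ± 0.25 and CPT2 by 2.75 ± 0.59. Desat3 and AK were saturated in diapause eggs on 1 array of 18 h, so their differences are not exact. In the other direction, hJHBP stood at -2.40 ± 0.59, DnaJ-5 at -2.12 ± 0.40, SPZ1 at -1.90 ± 0.30, serpin-8 at -1.56 ± 0.23 and eIF3-S9 at -1.09 ± 0.19. Serpin-8 was not well above background in either kind of egg at 18 h, so its difference restates its ratio at 30 h. The signal of hJHBP was well above it on 1 of 2 arrays in each kind. Tf was at 1.31 ± 0.23, Mef2 at 1.21 ± 0.25, Treh-2 at 1.19 ± 0.38, PBAN at 1.10 ± 0.52 and Kr-h1 at 1.05 ± 0.29. Over the alternatives run, Mef2 ranged from 0.514 to 2.23, Treh-2 from 0.792 to 2.4 and PBAN from 0.421 to 1.84.

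None of these differences passed over all probes in limma (0 of 13019, smallest adjusted p = 0.698). An unadjusted p under 0.05 was found for 878 probes (426 higher, 452 lower, 651 by chance), and the other limma fits also gave 0. Adjusted over the list alone, 6 list members passed: MLC-2, Mef2, Desat3, SPZ1, serpin-8 and Tf. In simulated data with the noise of these arrays, the test of the difference found 0% of 50 probes changed 8-fold, so the count of 0 says little about the size of the differences. Glyp was at -0.42 ± 0.19 and HSP70 at -0.55 ± 0.57, while Samui at 0.16 ± 0.24, Time at 0.04 ± 0.83 and Hsc70-4, saturated on several arrays, at -0.04 ± 0.77 each changed sign under another scaling.

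As a list, the ribosomal proteins moved towards higher ratios from 18 h to 30 h, with 54 of 74 genes above 0 and a median difference of 0.31, RpL29 being at 1.38 ± 0.35 and RpS29, saturated in diapause eggs on 1 array of 30 h, at 1.11 ± 0.34 (n = 4 arrays). Camera gave an adjusted p of 0.0057, which became 0.838 with an estimated correlation, 0.718 with the deposited ratios and 0.19 with median centring. The direction turned without replicate 2 of 30 h (adjusted p = 0.153), and without replicate 1 of 18 h the adjusted p was 0.094. Genes for cuticle and chitin moved the same way in 49 of 73 cases (median 0.12, camera adjusted p = 0.0406, and adjusted p = 0.838 with an estimated correlation). That call was lost without replicate 1 of 18 h (adjusted p = 0.094), replicate 2 of 18 h (0.465) or replicate 1 of 30 h (0.424), with the trend on probe GC content removed (0.119) and with the deposited ratios (0.0512). All 6 genes of the proteasome and ubiquitin list lay below 0 (adjusted p = 0.183), and 6 of 7 yolk and egg protein genes lay above 0 (0.087).

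In non-diapause eggs, 3 named genes rose between 18 h and 30 h. Pp, the precursor of paralytic peptide, rose 33.3-fold (log2 change 5.06 ± 0.40, SE, n = 2 arrays per time), from a signal well above background on 1 of the 2 arrays at 18 h. The chitinase gene Chi rose 7.5-fold (2.91 ± 0.24), with a second probe at 2.38 ± 0.20 and both probes named as cross-hybridising in the array annotation. Igflp, an insulin-like growth factor peptide, rose 4.43-fold (2.15 ± 0.18). These were 4 probes, all higher, each with a limma adjusted p of 0.047. Without 1 array the log2 change ranged from 4.24 to 5.84 for Pp, from 2.41 to 3.39 for Chi and from 1.70 to 2.60 for Igflp.

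The count rests on single arrays and on the scaling. It was 0 without replicate 2 of 18 h, without either array of 30 h, without normalization between arrays, with quantile normalization and without the filter on dim probes. It was 202 (128 higher, 74 lower, with the same 4 probes among them) without replicate 1 of 18 h and 109 without background correction. An unadjusted p under 0.05 was found for 1510 probes (835 higher, 675 lower, 651 by chance).

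Several other genes had large changes in non-diapause eggs that did not pass. The values were 5.32 ± 0.54 for hJHBP (n = 2 arrays per time, well above background on 1 array at 18 h), 5.19 ± 0.58 for CPG18, a glycine-rich cuticle protein, and 4.58 ± 0.76 for Time, with adjusted p of 0.0602, 0.0602 and 0.117. Serpin-8 and GlcNAcase3, a chitin-degrading hexosaminidase, were not well above background at 18 h, so that serpin-8 was at least 33.2-fold higher at 30 h and GlcNAcase3 at least 4.13-fold (adjusted p = 0.0765 and 0.0602). The limit of serpin-8 rests on single arrays, since its log2 change was 3.72 without replicate 1 of 30 h and 6.47 without replicate 2 of 30 h. Genes for melanin and sclerotisation had values of 3.60 ± 0.78 for Y-b, 2.47 ± 0.56 for Aanat, 2.30 ± 0.51 for tan and 1.42 ± 0.32 for PPO2, in a list with 5 of 11 genes above 0 (camera adjusted p = 0.204, median below 0 and mean and test up). The Hox gene Scr was at 1.82 ± 0.39, with 12 of 19 patterning genes above 0 (adjusted p = 0.234). Desat3 was at -2.98 ± 0.60. Of these genes, CPG18, hJHBP, GlcNAcase3, serpin-8 and Time passed without background correction. The first 4 of them also passed with an offset of 16. CPG18, hJHBP and GlcNAcase3 passed with the replicate number as a block, CPG18 with both channels above background on all arrays, and GlcNAcase3 without replicate 1 of 18 h. With that kind of egg alone and no spot correlation, CPG18, hJHBP, Time, Y-b and tan passed.

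Of the lists, cuticle and chitin (42 of 73 above 0), ribosomal proteins (55 of 74) and insulin signalling (6 of 12) passed camera as higher at 30 h in non-diapause eggs, with adjusted p of 0.0024, 0.0024 and 0.00579. With an estimated correlation none of these 3 calls held (adjusted p = 0.777 for each). Within them, RpL32 was at 1.57 ± 0.36 (n = 2 arrays per time), RpS29 at 1.09 ± 0.26 and the bombyxin genes Bbx-a2 and Bbx-a3, which encode insulin-like peptides, at 0.93 ± 0.17 and 0.73 ± 0.20. The insulin list also holds Igflp, which passed over all probes, so the call of that list partly restates it. Germ line genes (8 of 10 below 0), the cell cycle (11 of 15), heat shock proteins (19 of 23) and histones (3 of 4) passed as lower, with adjusted p of 0.00421, 0.00436, 0.00579 and 0.0152, and these were lost too with an estimated correlation (adjusted p = 0.777). Examples were nos-M at -1.97 ± 0.46 and Nanoso at -2.02 ± 0.57, both of the nanos family, Vlg, the vasa homologue, at -1.52 ± 0.45 and ovo at -0.78 ± 0.19. Further examples were cyclin A (Cyca) at -1.34 ± 0.37, Cdk7 at -1.23 ± 0.38, the histones H2a-l2 at -1.19 ± 0.23 and H2b-l, saturated on 1 array of 18 h, at -1.45 ± 0.37, Hsp23.7 at -2.05 ± 0.69 and DnaJ-13 at -0.59 ± 0.18. Fry called none of the 7 lists. Without normalization between arrays the histones were at an adjusted p of 0.419 and insulin signalling at 0.426, without replicate 1 of 18 h they were at 0.264 and 0.651, and the ribosomal proteins were at 0.902 without replicate 1 of 30 h. Without replicate 2 of 18 h the cell cycle was at 0.121 and cuticle and chitin at 0.053, and without replicate 2 of 30 h the histones were at 0.176 and insulin signalling at 0.0795. Adjusted over the list alone, 53 list members passed.

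Diapause genes in non-diapause eggs had values of -0.94 ± 0.30 for Samui (n = 2 arrays per time), -0.64 ± 0.15 for Glyp, -0.94 ± 0.69 for Treh-2, -0.26 ± 0.45 for PBAN, 0.30 ± 0.57 for HSP70 and 0.07 ± 0.54 for Hsc70-4, the last of which turned below 0 with quantile normalization and was saturated on 1 array of 18 h. E75 was at 1.24 ± 0.23, in an ecdysteroid list with 6 of 10 genes above 0 (adjusted p = 0.38, mean below 0 and test up).

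**Figure D3:**
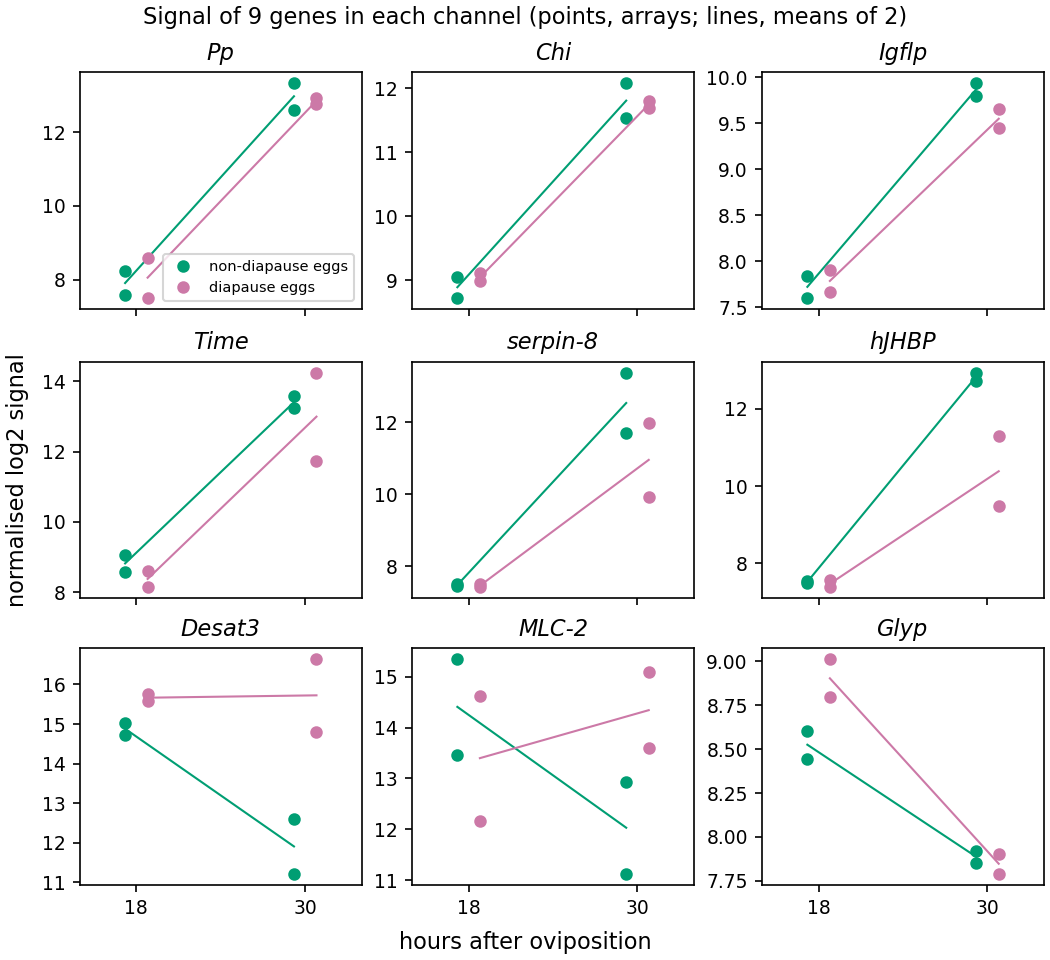
Normalised log2 signal (vertical axis) of 9 genes at 18 h and 30 h after oviposition (horizontal axis), with green points for the non-diapause channel and pink points for the diapause channel of each array, and lines through the means of 2 arrays. Pp, Chi and Igflp were higher at 30 h in both kinds of egg, and Desat3 had a mean of 11.90 in non-diapause eggs at 30 h against 15.72 in diapause eggs.

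In diapause eggs the same 3 genes had large values, Pp at 4.80 ± 0.40 (SE, n = 2 arrays per time), Chi at 2.70 ± 0.24 and Igflp at 1.76 ± 0.18, but no probe passed over all 4 arrays. CPG18 was at 4.81 ± 0.58, Time at 4.62 ± 0.76 and hJHBP at 2.92 ± 0.54, the last well above background on 1 of 2 arrays at each time. Over the alternatives run, hJHBP ranged from 1.5 to 4.39. Serpin-8 was at least 11.3-fold higher at 30 h, with a log2 change of 1.96 without replicate 1 of 30 h and 5.10 without replicate 2 of 30 h. Glyp was at -1.05 ± 0.15, well above background on 1 of 2 arrays at 30 h, Ago2, an Argonaute of the RNA interference pathway, at -1.63 ± 0.29 and Vlg at -1.82 ± 0.45.

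The smallest adjusted p in diapause eggs was 0.087, and 1994 probes had an unadjusted p under 0.05 (976 higher, 1018 lower, 651 by chance). The count of 0 in limma rests on the array of replicate 1 at 18 h. In the diapause channel of this array the log2 signals, centred on each probe's mean, correlated at -0.147 with those of replicate 2, against 0.465 between both 30 h arrays. It stood apart on the component of 16.5% of the variance. On the component of 53.7%, replicate 2 of 18 h lay furthest out, at -0.619 in the diapause and -0.474 in the non-diapause channel. Replicate 1 of 18 h lay at 0.0153 and -0.118 there. These values do not settle which 18 h array is unusual. Without this array 1040 probes passed, 473 higher and 567 lower at 30 h. These include Pp at 5.81, Chi at 2.77, Igflp at 2.22, CPG18 at 5.20, RpS29 at 2.33, E75 at 1.71, PPO2 at 2.13, Glyp at -1.11 and Vlg at -2.51 on the log2 scale. That fit has 1 diapause sample at 18 h, which is assumed to vary like the other groups. Leaving out any other array gave 0. No probe passed the test of the difference between the kinds of egg, so the changes over time are not shown to differ between diapause and non-diapause eggs.

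By camera with the preset correlation, 13 lists passed between 18 h and 30 h in diapause eggs. None of these calls held with an estimated correlation, where the adjusted p lay between 0.406 and 0.495, or in fry. The ribosomal proteins (68 of 74 above 0, adjusted p = 8.27e-11) and cuticle and chitin (58 of 73, 6.64e-09) passed as higher at 30 h, with RpS29 at 2.21 ± 0.26 (n = 2 arrays per time, saturated on 1 array of 30 h), RpL32 at 2.18 ± 0.36, RpL29 at 2.00 ± 0.34 and CPH31 at 2.16 ± 0.34. Yolk and egg proteins (5 of 7, 0.00108), insulin signalling (9 of 12, 0.00113), the nervous system (32 of 51, 0.0029), immune genes (11 of 17, 0.0144), ecdysteroid genes (6 of 10, 0.0185), muscle (4 of 6, 0.0278) and melanin (7 of 11, 0.0278) passed as higher too. Their members included the vitellogenin gene VG at 1.33 ± 0.23, well above background on 1 of 2 arrays at 18 h, Lp-c6 at 1.10 ± 0.18 and Bbx-a2 at 1.22 ± 0.17, with Bbx-a3 at 1.08 ± 0.20 and the odorant-binding protein gene Obp4 at 2.43 ± 0.49, both also on 1 of 2 arrays at 18 h. Others were Ash2 at 1.60 ± 0.28, cact at 1.12 ± 0.21, Defensin, an antimicrobial peptide, at 2.05 ± 0.77, which ranged from 0.98 to 3.17 without 1 array. Also among them were E75 at 1.62 ± 0.23, the ecdysone receptor gene EcR at 1.08 ± 0.28, Mef2 at 1.74 ± 0.27, PPO2 at 2.00 ± 0.32 and Y-b at 3.27 ± 0.78. Germ line genes (9 of 10 below 0, 0.0029), heat shock proteins (19 of 23, 0.00975), the cell cycle (11 of 15, 0.0406) and the proteasome list (5 of 6, 0.0406) passed as lower, with nos-M at -1.44 ± 0.46, DnaJ-8 at -1.21 ± 0.26, Cdk7 at -1.32 ± 0.38 and Ubc13 at -0.83 ± 0.20.

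Under the preset correlation, the calls of the ribosomal proteins, cuticle and chitin and germ line genes held without any 1 array, and each of the others was lost without at least 1. Without replicate 1 of 18 h the adjusted p was 0.352 for yolk, melanin and the proteasome, 0.111 for insulin signalling, 0.0875 for the nervous system, 0.102 for immune genes, 0.463 for ecdysteroid genes and 0.122 for muscle. Without replicate 2 of 18 h it was 0.1 for heat shock proteins and 0.229 for the cell cycle. Adjusted over the list alone, 38 list members passed. Samui was at -0.79 ± 0.30 (n = 2 arrays per time), PBAN at 0.84 ± 0.45, HSP70 at -0.25 ± 0.57 and Hsc70-4 at 0.03 ± 0.54, which turned below 0 with quantile normalization and was saturated in diapause eggs on 2 arrays of 18 h and 1 of 30 h. Treh-2 was at 0.25 ± 0.69, with another probe of opposite sign and a value of -0.40 without normalization between arrays.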

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

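The tests of the weak relation between arrays were fixed before their results were seen, and the GC correction of the lists was chosen after.

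For 2 gene lists the test of the difference between 30 h and 18 h passed in camera. The ribosomal proteins had an adjusted p of 0.0057, with 54 of 74 genes above 0, and cuticle and chitin had an adjusted p of 0.0406, with 49 of 73 above 0. Both were lost with an estimated correlation (adjusted p = 0.838 for each), and over the other alternatives the adjusted p of the ribosomal list lay between 9.28e-21 and 0.815, with the direction turned without replicate 2 of 30 h (adjusted p = 0.153).

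Both arrays of a time had log2 ratios with little in common, at correlations across probes of 0.108 at 18 h and 0.162 at 30 h. Dim spots are argued against, since the correlation among the brightest probes was 0.0909 at 18 h and 0.163 at 30 h. Measurement error of spots is argued against by duplicate spots, whose correlation was 0.962 or more on every array. Noise of single probes is argued against, since the difference between both arrays of a time correlated at 0.521 at 30 h and 0.709 at 18 h between probes of the same gene, where such noise would give values near 0. Differences between egg samples or labelling reactions stay open and untested, since the labels give no batch within a time.

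Ratios shared by all 4 arrays could come from the dyes, since no array had them swapped. The mean ratio correlated at 0.151 with probe GC content, at -0.0874 and -0.106 on the replicate 1 arrays of 18 h and 30 h and at 0.253 and 0.259 on the replicate 2 arrays. The sign thus followed the replicate number at both times, and a dye effect of base composition stays open. Ratios correlated at 0.158 between the replicate 2 arrays of both times and at -0.0323 between the replicate 1 arrays. The former value was near those between arrays of 1 time, 0.108 and 0.162. Replicate 1 of 18 h correlated at -0.251 with replicate 2 of 30 h, and replicate 2 of 18 h at 0.00124 with replicate 1 of 30 h. A dye effect of single probes cannot be told apart from a difference between the eggs, since 0 genes had a called probe and a second probe to compare. This holds for genes with the same sign on all 4 arrays, such as E75, Run, GSTd2 and Samui, which were above 0 on each.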

How the results depend on the processing

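Alternatives that removed a GC trend, kept specific probes alone or left out saturated probes were chosen after seeing the data, as were the replicate block of the lists and, for lists over time, leaving out normalization between arrays. The ratio comparisons gave 0 probes under every alternative that was run, with 0.064 as the smallest adjusted p, at 30 h with the deposited value table. Of 2714 values of named genes, 2612 kept their direction and their side of the threshold, 19 were weaker, 41 stronger and 42 reversed. These counts overstate stability, since several alternatives leave a ratio unchanged and most genes kept their side by still not passing. With the main settings only Pp, Chi and Igflp passed, in non-diapause eggs over time. All 19 weaker values were theirs, from 11, 12 and 12 alternatives run for these genes. Of 351 values of called lists, 213 were the same, 136 weaker and 2 reversed. Signal over background limits serpin-8, hJHBP, Pp and GlcNAcase3 at 18 h.

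For non-diapause eggs over time, the count of 4 became 0 without normalization between arrays, 0 with quantile normalization, 0 without the filter, 109 without background correction, 42 with an offset of 16, and 15 with both channels above background on all arrays. It was 66 with the replicate block, 45 with that kind of egg alone and no spot correlation, and 0 to 202 without 1 array. For diapause eggs it was 0 to 1040 without 1 array. The 8 list calls of the ratio comparisons became 0 with an estimated correlation, 0 in fry, 4 with the mean over probes, 16 with all probes, 5 with median centring, 2 with the deposited ratios and 5 to 10 without 1 array. The 20 calls over time became 0 with an estimated correlation, 0 in fry and 11 to 25 without 1 array. The cause was not tested, except that fits without 1 array have fewer samples and leave a lone array assumed to vary like the others.

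Values near 0 turned in direction. HSP70 at 18 h was -0.00162 without background correction, -0.00997 with the deposited ratios, -0.01 with the deposited value table and -0.141 with arrays scaled to one spread. Hsc70-4 without background correction was 0.0102 at 18 h, 0.0279 at 30 h and 0.0177 for the difference. It was 0.391 and 0.107 at 18 h and 30 h with median centring, and 0.674 at 30 h and 0.691 for the difference with arrays scaled. It was 0.0059 for the difference with the GC trend removed, and with quantile normalization -0.0681 in non-diapause and -0.233 in diapause eggs over time. With median centring Glyp at 30 h was 0.0287, the difference of Samui -0.135 and that of Time -0.0478, which was -1.08 with arrays scaled and -0.0167 with the GC trend removed. Treh-2 in diapause eggs was -0.4 without normalization between arrays. The cause was not tested. Median centring moved the median of all probes at 18 h to 0.143, and leaving out normalization between arrays moved it to -0.33 in non-diapause and -0.323 in diapause eggs over time.

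Without 1 array, ranges were -0.0594 to 0.214 for PBAN, -0.348 to 0.443 for HSP70 and -0.918 to 0.0346 for Time at 18 h. At 30 h they were -1.14 to 1.03 for Hsc70-4, -1.17 to 0.172 for HSP70 and -1.48 to 0.674 for Time. For the difference they were -1.04 to 1.12 for Time, -0.0586 to 0.37 for Samui, -1.12 to 1.04 for Hsc70-4 and -1.22 to 0.124 for HSP70. They were -0.783 to 0.186 for PBAN, -0.103 to 0.712 for HSP70 and -0.506 to 0.637 for Hsc70-4 in non-diapause eggs. In diapause eggs they were -0.803 to 1.20 for Treh-2, -1.05 to 0.559 for HSP70 and -0.487 to 0.532 for Hsc70-4. The adjusted p of the ribosomal list ranged from 2.18e-14 to 0.0435 at 30 h, where it turned up without replicate 1 of 30 h (1.12e-07), and from 9.28e-21 to 0.153 for the difference, where it turned down without replicate 2 of 30 h.

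With the replicate number as a block, the ratio comparisons stayed at 0 and diapause eggs over time at 0, and the lists had 6 and 18 calls. The ommochrome list (adjusted p = 0.0726) and the immune list (0.145) at 30 h and the cell cycle (0.104) and proteasome (0.0894) in diapause eggs lost their calls. The spot correlation was -0.567 with the block and 0.951 without normalization between arrays, against 0.292, so the cause of the count of 66 was not tested apart from this change.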

Other observations

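The tests in this part were chosen after the ratios at 30 h had been seen.

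Desat3, AK, Y-fa and MLC-2 had mean log2 signals at 30 h of 15.72, 15.39, 15.43 and 14.34 in diapause eggs and 11.90, 13.04, 12.59 and 12.03 in non-diapause eggs. At 18 h the means were 15.67, 15.38, 14.55 and 13.40 in diapause eggs and 14.88, 15.80, 13.99 and 14.41 in non-diapause eggs, so the lowest of the 4 means was in non-diapause eggs at 30 h for each gene. Their choice by high ratios at 30 h favours this. Other genes with high ratios at 30 h differed, since from 18 h to 30 h the non-diapause mean rose from 8.995 to 9.52 for Mef2 and from 11.71 to 12.79 for Cyp332a1. Desat3 and AK were saturated in diapause eggs on 1 array of 18 h. Serpin-8 and hJHBP had means of 12.54 and 12.84 in non-diapause eggs and 10.96 and 10.38 in diapause eggs at 30 h, and between 7.46 and 7.52 in both kinds at 18 h.

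A candidate explanation is that diapause eggs lag behind non-diapause eggs between 18 h and 30 h, so that genes falling over time in non-diapause eggs have high ratios at 30 h. With the main settings the changes over time were not fewer in diapause eggs. In limma, 1994 probes had an unadjusted p under 0.05 there, against 1510 in non-diapause eggs. Without normalization between arrays the counts were 62 and 145, and with that kind of egg alone and no spot correlation 1674 and 1763. The order of these counts also turned without replicate 2 of 30 h, so it does not decide on a lag. With the change over time and the ratio taken from different arrays, the correlations across probes were -0.188 for the change on the replicate 2 arrays and -0.309 for that on the replicate 1 arrays, and with probe GC content and mean intensity partialled out they were -0.18 and -0.335. In the same order the correlations with the 18 h ratio were 0.396 and -0.0394, at least 0.27 above those with the 30 h ratio. This excess does not bear on a dye bias that is the same on every array, since such a bias cancels in the change within a channel. Signals of non-diapause eggs at 30 h enter the change and the 30 h ratio with opposite signs. Those at 18 h enter the change and the 18 h ratio with the same sign. Any trait of the non-diapause samples that replicates share thus lowers the correlation at 30 h and raises that at 18 h. The correlations cannot tell a lag from such a trait. The lag stays a hypothesis, also since the arrays are too few to set these correlations against their spread, and probes are not independent replicates.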
